A study of Mus musculus with 4 samples.

How the data were processed

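Epithelial cells were isolated from lungs of mouse embryos at embryonic day 12.5, total RNA was extracted on silica columns and polyadenylated RNA was captured on beads, per the labels' protocols. The design text of the series speaks of nuclei, whereas the labels of these 4 libraries speak of isolated cells, and the labels were followed. The submitters' processing notes name cutadapt 2.5, HISAT2 2.2.1, StringTie 2.2.1, DESeq2 1.38.3 and the genome build mm10, without their roles or settings. Strand handling, the annotation release and read depth are not given in the sources used here.

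The deposited table has 18390 genes. Per the file headers it holds TPM for each library, scaled by the authors to gene length and to the library total. Per the file headers it also holds a baseMean over all libraries, a normalized signal with no value per library. The authors' log2 fold change and its standard error, a test score, a p-value and an adjusted p-value are per the file headers too. The columns with the letters C and K and the numbers 1 and 2 were read as CTRL and CKO replicates 1 and 2, since the letter K occurs only in the label CKO. No raw counts were used, so no count model was run.

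Genes with at least 1 TPM in at least 2 of the 4 libraries were tested, 14485 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with a variance trend, two-sided, and Benjamini-Hochberg (BH) adjusted p under 0.05 was the threshold. Every adjusted p printed for a gene is limma's unless the authors' deposited table is named. Log2 changes are CKO minus CTRL on the log2(TPM + 1) scale, which understates the change of genes with low TPM; folds and percentages are ratios of group mean TPM. On simulated data with 14485 genes and 200 changed genes of 5 TPM or more, for this comparison and over 20 draws, 21.1% of changes of 1 log2 unit, 73.3% of those of 2 and 95.5% of those of 3 were recovered, with 4.87% false calls. A gene that did not pass may therefore still have changed by 1 log2 unit. The simulation drew its variances from limma's own fitted model with independent errors, so its share of false calls was nearly set by construction. It does not test whether that model holds for these libraries.

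The 31 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took 14 genes named in advance, the 10 largest rises and 10 largest falls past the threshold with both CKO values outside the CTRL range and a group mean of at least 5 TPM, and up to 4 members of each list by smallest p. Genes outside it are said to be chosen after their values were seen. Lists were tested with limma's camera at a preset correlation of 0.01, with BH adjustment over the 31 lists. Of 5 lists past the threshold, 0 held with an estimated correlation (1 list had an unadjusted p under 0.05 there) and 1 held with limma's fry, the p53 targets. fry tests whether a list moves on balance in 1 direction. Its mixed form counts changes in either direction, and 14 lists passed it. Neither form compares a list with other genes. Those 14 included the distal tip, FGF, WNT, proximal airway, Hox and imprinted lists, none of which passed with camera. The hypoxia list has 17 entries for its symbols because 1 symbol occurs with a pair of gene IDs.

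Gene positions came from the GENCODE annotation of the mouse assembly GRCm38, which is mm10. Of 18390 gene IDs, 18375 matched without their version and 18005 with it. Neighbouring genes, the sequence motif and the mitochondrial genome were tested with Python 3 libraries by shuffles, Fisher's exact test and permutation. The alternatives were other pseudocounts (0.1 and 5), no filter, a filter at 5 TPM, quantile and median-ratio scaling, a replicate block, no variance trend, leaving out each library, a fold of at least 1.5 and the authors' deposited table. After the data were seen, fits without X and Y genes and with TPM rescaled without mitochondrial genes were added, and the authors' deposited calls were recounted.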

Results

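The series title names CTCF, a DNA-binding protein that shapes chromatin loops and insulates regulatory domains, in lung development. Polyadenylated RNA was sequenced from mouse lung epithelial cells isolated at embryonic day 12.5, when the lung buds branch. There were 4 libraries in 2 groups, CTRL and CKO, with 2 libraries per group. The labels do not spell out CKO or say whether replicates came from separate embryos or litters, so p-values measure the spread between these libraries. For the CKO pair that spread may be technical. In CTRL, 4 Y-linked genes together held 64.8 TPM in replicate 1 and 0.0217 TPM in replicate 2. Xist stood at 0.0512 and 10.7 TPM. These values argue against technical replicates of the same embryo for the CTRL pair. TPM, a transcript abundance scaled to gene length and library total, was given for 18390 genes, and between 13850 and 14328 genes reached 1 TPM in a library. TPM keeps no depth, so read depth per library is unknown here and gives no counting interval. Pearson correlations of log2 TPM were 0.965 between the CTRL libraries, 0.951 between the CKO libraries, and 0.929 to 0.942 across groups.

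Ctcf, inferred to be the targeted gene because the series title names CTCF, was lower in both CKO libraries. Ctcf (ENSMUSG00000005698.15; mm10 chromosome 8, 105636568 to 105682922, plus strand) stood at 98.7 and 109.7 TPM in CTRL replicates 1 and 2, and at 30.5 and 53.1 TPM in CKO replicates 1 and 2. The means were 104 ± 7.80 TPM (SD, n = 2) and 41.8 ± 16.0 TPM (SD, n = 2), so CKO held 40.1% of the CTRL level. The log2 change was -1.35 (SE 0.253, limma, BH-adjusted p = 0.0389). The call was lost without CTRL replicate 1 (log2 change -1.42) and without CTRL replicate 2 (-1.27), while the direction stayed. Gene-level TPM counts all annotated exons, and which part of Ctcf may have been deleted is not given in the sources used here.

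Which genes differed between CKO and CTRL epithelium was the only contrast in the labels. Of 14485 genes tested, 243 passed the limma threshold, 127 of them higher and 116 lower in CKO. Among the 31 lists, genes that p53 activates had the most rises, and Sftpc, Sox2, Krt8 and Krt18 were among the genes that fell. The median log2 change of all tested genes was -0.11, and median-ratio scaling moved it to -0.0025, so list medians are also given relative to it. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, and the calls rest on limma's pooling of the spread across genes. The total was 126 without CTRL replicate 1, 125 without CTRL replicate 2, 617 without CKO replicate 1 and 1268 without CKO replicate 2, and 79 genes (51 higher, 28 lower) passed in all of these fits as well. Without the trend in limma's variance model the total was 8.

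**Figure D1:**
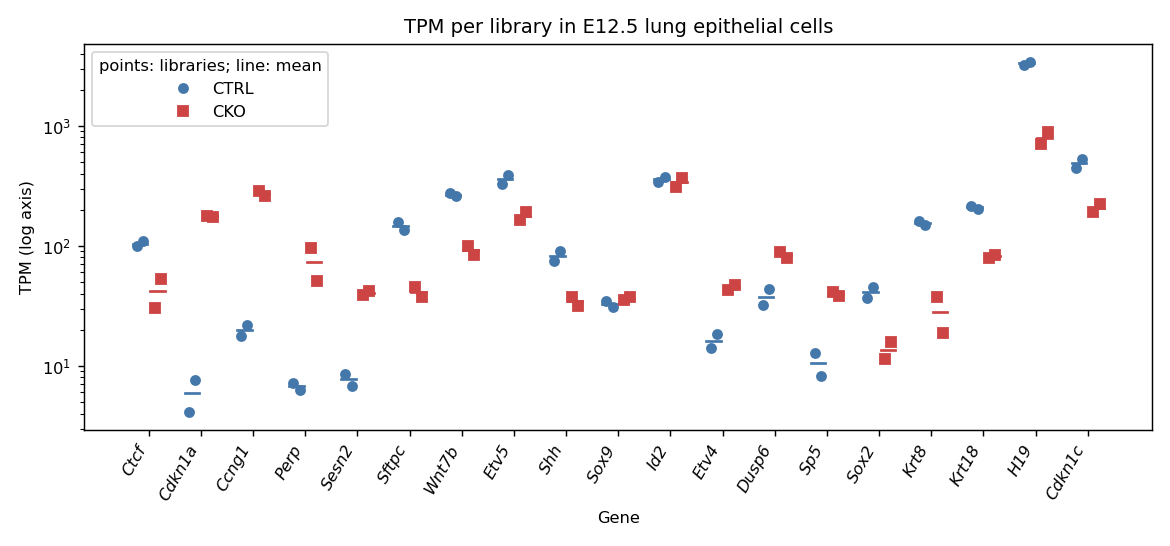
TPM on a log axis for 19 genes in each of the 4 libraries (blue circles CTRL, red squares CKO, short lines the group means, n = 2). Cdkn1a rose from a mean of 5.88 to 176 TPM, whereas Sox9 and Id2 differed by less than the replicate spread allowed limma to call.

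Many p53 target genes were higher in CKO. Of 24 tested members of this list, 14 were higher, none was lower and 10 did not pass; adjusted over the list alone, 17 were higher and 1 was lower. At an unadjusted p under 0.05 19 members passed, and the authors' deposited table marked 19 up and 1 down. Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067.14; chromosome 17, 29090976 to 29100727), went from 5.88 ± 2.53 to 176 ± 1.06 TPM (SD, n = 2 each), a 29.9-fold rise in mean TPM (log2 change 4.73, SE 0.274, adjusted p = 1.3e-04, limma). Ccng1, which encodes cyclin G1, rose 13.8-fold to 272 ± 18.96 TPM (SD, n = 2). Perp, a desmosomal and pro-apoptotic p53 target, rose 10.8-fold, and Sesn2, a stress-induced regulator of mTORC1, rose 5.24-fold. Eda2r, which encodes a TNF receptor family member, had the largest log2 rise among genes named by the rule, 5.34 (SE 0.383). The list had a median log2 change of 1.31, or 1.43 relative to all genes, and camera with a preset correlation gave an adjusted p of 1.79e-21 (range without each library 5.16e-23 to 2.47e-14). With an estimated correlation the adjusted p was 0.255, and fry gave 0.0318. The correlation estimated for this list was -0.020, under the preset of 0.01, so a higher correlation was not why the call was lost. Cdkn1a, Ccng1, Perp and Sesn2 passed in every fit that left out 1 library; Eda2r fell under the filter without either CKO library and was then not tested.

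Markers of the distal tip, where branching progenitors sit, moved in both directions. Of 18 tested members, 2 were higher, 5 were lower and 11 did not pass; adjusted over the list alone, 3 were higher and 6 lower. Sftpc, the surfactant protein C gene, fell from 146 ± 15.6 to 41.2 ± 5.62 TPM (SD, n = 2 each), to 28.3% of CTRL (log2 change -1.80, SE 0.180, adjusted p = 0.00271, limma). Wnt7b, an epithelial WNT ligand, fell to 34.6% of CTRL, Shh, a hedgehog ligand, to 41.6%, and Etv5, a transcription factor induced by FGF, to 49.5%. Hmga1, named after its value was seen, fell to 56.3%. Etv4, also induced by FGF, rose 2.79-fold, and Dusp6, which encodes an ERK phosphatase, rose 2.23-fold. Sox9 stood at 32.8 ± 2.56 and 36.5 ± 1.70 TPM, Id2 at 359 ± 24.98 and 338 ± 41.0 TPM, Mycn at 46.5 ± 3.25 and 45.6 ± 12.3 TPM, and Bmp4 at 31.4 ± 2.09 and 43.9 ± 2.97 TPM in CTRL and CKO (SD, n = 2 each), and none of them passed in limma. Fgfr2, the receptor for FGF10, had a log2 change of -0.73 (SE 0.158) and an adjusted p of 0.0684 in limma; it passed with a filter at 5 TPM and without CKO replicate 2 (-0.86). The authors' deposited table marked Fgfr2 down (log2 fold change -0.66, adjusted p = 2.88e-11) and Bmp4 up (0.61, adjusted p = 0.00764). The list median relative to all genes was -0.03 and the camera adjusted p was 0.893. fry's mixed test, which counts changes in either direction, gave an adjusted p of 0.00518. Without CTRL replicate 1 the calls of Shh, Etv4, Dusp6 and Hmga1 were lost, with log2 changes of -1.38, 1.25, 0.94 and -0.85. Without CTRL replicate 2 those of Shh, Etv5 and Hmga1 were lost, with log2 changes of -1.10, -0.89 and -0.81. Dusp6 was also not called with a pseudocount of 0.1 or no filter, nor Hmga1 with median-ratio scaling.

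Signalling lists that share these genes gave few further limma calls. The authors' deposited table marked 6 up and 3 down in the FGF list, and 5 up and 3 down in the WNT list. fry's mixed test gave these 2 lists adjusted p of 0.00518 and 0.00406. FGF feedback genes had 2 higher (Etv4, Dusp6) and 1 lower (Etv5) of 16 tested, with a median of 0.36 relative to all genes and a camera adjusted p of 0.157; adjusted over the list alone, 5 were higher and 4 lower. WNT genes had 1 higher and 1 lower of 22 tested (3 and 4 adjusted over the list alone; camera adjusted p = 0.811). The higher one was Sp5, a WNT target, which rose 3.77-fold from 10.6 ± 3.26 to 40.0 ± 2.03 TPM (SD, n = 2 each), and the lower one was Wnt7b. Sp5 did not pass without CTRL replicate 2 (log2 change 1.56). Of 13 hedgehog pathway genes, Shh alone was lower (3 lower adjusted over the list alone; camera adjusted p = 0.434). BMP and TGF-beta feedback genes had no call among 17 tested and Notch pathway genes none among 16, with 2 and 0 lower adjusted over the list alone and camera adjusted p of 0.893 and 0.484. At an unadjusted limma p under 0.05 they had 6 and 0, and the authors' deposited table marked 3 up and 3 down in the BMP list and 1 up in the Notch list. Relative to all genes the BMP list had a median of 0.10 and a mean of -0.02, and the WNT list 0.02 and -0.04. For both lists camera pointed up, whereas fry's test of movement in 1 direction pointed down, and neither passed.

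A few airway and epithelial genes were lower in CKO, while most members of both lists did not pass. Sox2, the transcription factor of proximal airway, fell from 41.1 ± 6.32 to 13.6 ± 2.98 TPM (SD, n = 2 each), to 33.1% of CTRL (log2 change -1.54, SE 0.261, adjusted p = 0.0261, limma). Of 12 proximal airway genes tested, 0 were higher and 3 were lower, namely Sox2, Cldn10 and Ccno (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.258). The median of this list was -0.23 and its mean 0.36 relative to all genes, so they differ in sign, and the camera test pointed down. Of its members that did not pass, Scgb1a1 and Krt5 were each high in a single CKO library. Scgb1a1 stood at 2150 TPM in CKO replicate 2 and Krt5 at 55.8 TPM in CKO replicate 1. Krt5 was also at 4.33 TPM in CKO replicate 2, against 0 in both CTRL libraries, and the authors' deposited table marked it up. Scgb1a1 was named after its values were seen. At an unadjusted limma p under 0.05 5 members passed, and the authors' deposited table marked 1 up and 4 down. Cldn10 (log2 change -1.75) was not called without CTRL replicate 1 (-1.64) or without CTRL replicate 2 (-1.85), and neither was Sox2 (-1.69 and -1.38). Ccno fell under the filter without either CTRL library and was then not tested. The calls of Cldn10 and Ccno were also lost with the replicate block, quantile or median-ratio scaling, a pseudocount of 0.1, no filter, and TPM rescaled without mitochondrial genes. Of 25 genes of epithelial identity and junctions, 3 were lower and 22 did not pass (8 lower adjusted over the list alone). They were Krt8 and Krt18, the paired keratins of simple epithelia, at 17.9% and 39.1% of CTRL, and Cldn18, a tight junction claudin, at 42.0%. Krt8 held 162 and 150 TPM in CTRL and 37.4 and 18.7 TPM in CKO. Nkx2-1, the lung lineage transcription factor, had a log2 change of -0.57 (SE 0.146; limma adjusted p = 0.123) and Epcam one of -0.60 (SE 0.128; adjusted p = 0.0669). Nkx2-1 passed without CKO replicate 2 (-0.60), and Epcam passed without CKO replicate 1 (-0.63), without CKO replicate 2 (-0.56) and with a filter at 5 TPM. The list had a median of -0.27 relative to all genes and a camera adjusted p of 0.00739. That call was lost without CKO replicate 2 (adjusted p = 0.328; range without each library 3.59e-04 to 0.328), and the adjusted p was 0.965 with an estimated correlation. Cldn18 was not called without CTRL replicate 1 (log2 change -1.19) or without CTRL replicate 2 (-1.25).

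Alveolar and neuroendocrine markers each gave 1 call. Among 14 alveolar type 1 and type 2 genes only Sftpc passed (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.95). Among 3 neuroendocrine genes tested, Uchl1, a deubiquitinase of neurons and neuroendocrine cells, rose 1.77-fold to 223 ± 8.03 TPM (SD, n = 2; limma adjusted p = 0.0263), and the list had a camera adjusted p of 0.419 (1 higher adjusted over the list alone). Its call was lost without CTRL replicate 1 (log2 change 0.84) and without CTRL replicate 2 (0.80).

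**Figure D2:**
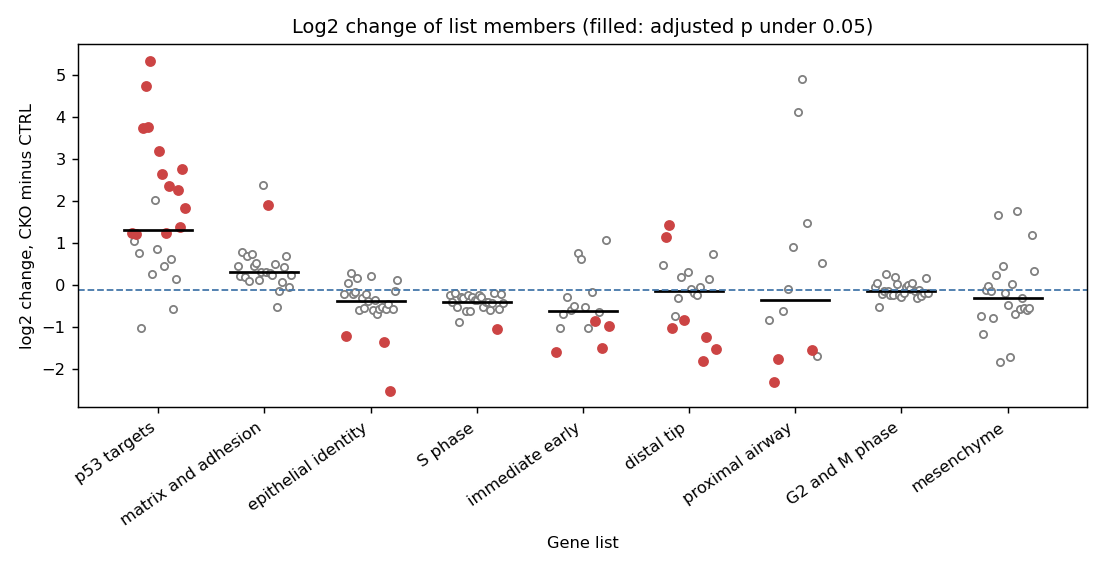
Log2 change of each tested member of 9 gene lists (circles; filled red where the limma adjusted p was under 0.05), with the list median (black line) and the median of all genes (blue dashes at -0.11). The p53 targets have a median of 1.31 and 14 filled points, all above 0.

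Among proliferation genes 1 passed in limma. Of 25 genes of DNA replication and S phase, Rrm2, a subunit of ribonucleotide reductase, was lower at 48.9% of CTRL and 24 did not pass (1 lower adjusted over the list alone). All 25 had a log2 change below 0, also with quantile and median-ratio scaling, 11 of them at an unadjusted limma p under 0.05, and the authors' deposited table marked 2 down. Without CTRL replicate 2, 24 were below 0. The relative median was -0.28, with a camera adjusted p of 7.62e-04 (range without each library 0.00583 to 0.00987) and an adjusted p of 0.965 with an estimated correlation. None of 25 genes of G2 and mitosis passed in limma, adjusted over the list alone or at an unadjusted p under 0.05, and the authors' deposited table marked 0; their relative median was -0.03 and the camera adjusted p 0.951. Mki67, a proliferation marker, stood at 39.9 ± 13.0 and 38.3 ± 21.2 TPM (SD, n = 2 each). Rrm2 was not called without CTRL replicate 1 (log2 change -1.14) or without CTRL replicate 2 (-0.95), nor with a pseudocount of 0.1 or no filter.

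Among basement membrane and adhesion genes 1 passed in limma. At an unadjusted limma p under 0.05 there were 8, and the authors' deposited table marked 8 up and 0 down. Of 24 tested, Lama1, the laminin alpha 1 chain, rose 4.13-fold to 27.6 ± 1.87 TPM (SD, n = 2) and 23 did not pass (3 higher adjusted over the list alone). The relative median was 0.43 and the camera adjusted p 2.98e-05 (range without each library 1.21e-05 to 0.00428), against an adjusted p of 0.965 with an estimated correlation. Of the 24 members 21 were above 0 and 3 below, against 15 and 9 without CTRL replicate 1. Lama1 did not pass without CTRL replicate 1 (log2 change 1.71). Immediate early genes, which respond to cell dissociation, had 4 of 16 members lower (Nr4a1, Atf3, Zfp36 and Jund) and 12 that did not pass, with 1 higher and 10 lower adjusted over the list alone. Nr4a1 fell to 35.5% and Atf3 to 33.3% of CTRL. The relative median was -0.50, and the camera adjusted p was 0.025, 0.207 without CKO replicate 2, 0.0623 without CTRL replicate 2, and 0.965 with an estimated correlation; the range without each library was 0.00275 to 0.207. Atf3 lost its call without CTRL replicate 2 (log2 change -1.48), and Jund and Zfp36 lost theirs without CTRL replicate 1 (-0.95 and -1.01) and without CTRL replicate 2 (-0.76 and -0.95). Integrated stress genes had 1 higher (Sesn2) and 1 lower (Atf3) of 15 tested (2 and 1 adjusted over the list alone; camera adjusted p = 0.874), and their median was -0.08 but their mean 0.06 relative to all genes, with a test that pointed up. Hypoxia and glycolysis had 1 lower of 17 tested, Bnip3, a mitophagy receptor, at 43.1% of CTRL (4 lower adjusted over the list alone; camera adjusted p = 0.0583). Bnip3 was not called without CTRL replicate 1 (log2 change -1.04) or without CTRL replicate 2 (-1.35). Its call was also lost with the replicate block, and it and Zfp36 were not called with median-ratio scaling, a pseudocount of 0.1, no filter, or TPM rescaled without mitochondrial genes. None of 6 interferon-response genes passed in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 marked in the authors' deposited table; camera adjusted p = 0.893).

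Loci at which CTCF is known to act gave calls at a few genes. H19, the imprinted noncoding RNA beside a CTCF-bound control region (chromosome 7, 142575529 to 142578143, minus strand), fell from 3329 ± 152 to 799 ± 137 TPM (SD, n = 2 each), to 24.0% of CTRL (log2 change -2.07, SE 0.156, adjusted p = 7.13e-04, limma). Cdkn1c, an imprinted cell cycle inhibitor on the same chromosome at 143458339 to 143461050, fell to 42.6%. Both passed in every fit that left out 1 library. The other 23 of 25 imprinted genes tested did not pass (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.484). The list's relative median, its relative mean and camera pointed up, whereas fry pointed down. Of 17 clustered protocadherins tested, Pcdhga7 was lower at 7.43% of CTRL (1 lower adjusted over the list alone; camera adjusted p = 0.893); these genes share their last exons, so their values are uncertain. Pcdhga7 stood at 10.9% of CTRL without CKO replicate 1 and 4.005% without CKO replicate 2. It did not pass without CTRL replicate 1 (log2 change -2.99) or without CTRL replicate 2 (-2.33), nor with a pseudocount of 0.1 or no filter. None of 16 Hox genes passed (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.291), and none of 18 genes of cohesin and its partners did (0 adjusted over the list alone; camera adjusted p = 0.951). Each of these 2 lists had 3 genes at an unadjusted limma p under 0.05, and the authors' deposited table marked 1 Hox gene up and 1 down and 1 gene of the cohesin list up.

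The lists of markers of other cell types gave no limma call, which does not show that the cell composition of the groups was alike. The lists were mesenchyme (23 tested), mesothelium (8), endothelium (6), neural crest and neurons (6), erythroid cells (4), immune cells (2) and other foregut endoderm (8), with camera adjusted p of 0.893, 0.823, 0.95, 0.488, 0.893, 0.552 and 0.874. Adjusted over the list alone, 1 gene was higher among neural genes and 0 passed in the other lists. At an unadjusted limma p under 0.05 there were 6 mesenchyme, 4 mesothelium, 1 neural and 1 endoderm genes and 0 in the others. The authors' deposited table marked 1, 2, 1 and 1 of these lists up and 1 endoderm gene down. Relative medians and means differed in sign for endothelium (-0.17 and 0.04, with a test that pointed down) and mesothelium (-0.16 and 0.25, with a test that pointed up). The labels call the embryos male, and 3 libraries carried Y-linked transcripts: Ddx3y, Eif2s3y, Kdm5d and Uty together held 64.8 TPM in CTRL replicate 1, 72.9 in CKO replicate 1 and 68.3 in CKO replicate 2. CTRL replicate 2 held 0.0217 TPM of these and 10.7 TPM of Xist, against 0.0512 TPM of Xist or less in the others. These values argue against the male label for CTRL replicate 2, so sex was not balanced between the groups. Only 2 called genes lay on X and 0 on Y, so a fit without them could change the count little. An effect of sex on autosomal genes was not tested. With X and Y genes left out, an alternative added after the data were seen, 243 genes passed, 241 of them shared with the fit to all genes; the sex list had 4 genes tested and no limma call (0 adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 marked in the authors' deposited table; camera adjusted p = 0.0583).

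Mitochondrially encoded RNA made up 20.5% and 14.99% of TPM in CTRL replicates 1 and 2, and 25.4% and 20.8% in CKO replicates 1 and 2. The valine tRNA mt-Tv rose from 25.2 ± 1.40 to 530 ± 169 TPM and the isoleucine tRNA mt-Ti from 66.9 ± 10.3 to 994 ± 19.98 TPM (SD, n = 2 each), with log2 changes of 4.31 and 3.88. Of 2 genes named after their values were seen, the large ribosomal RNA mt-Rnr2 had a log2 change of 1.61 (SE 0.202; limma adjusted p = 0.00678), whereas mt-Co1 had one of -0.19 (SE 0.207; adjusted p = 0.77). None of the 13 mitochondrial protein-coding genes passed in limma (2 higher adjusted over the list alone, 6 at an unadjusted p under 0.05 and 1 marked up in the authors' deposited table; camera adjusted p = 0.0583). Polyadenylated RNA was selected and the strand setting is not given in the sources used here, so reads over tRNA positions can come from longer or antisense transcripts.

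**Figure D3:**
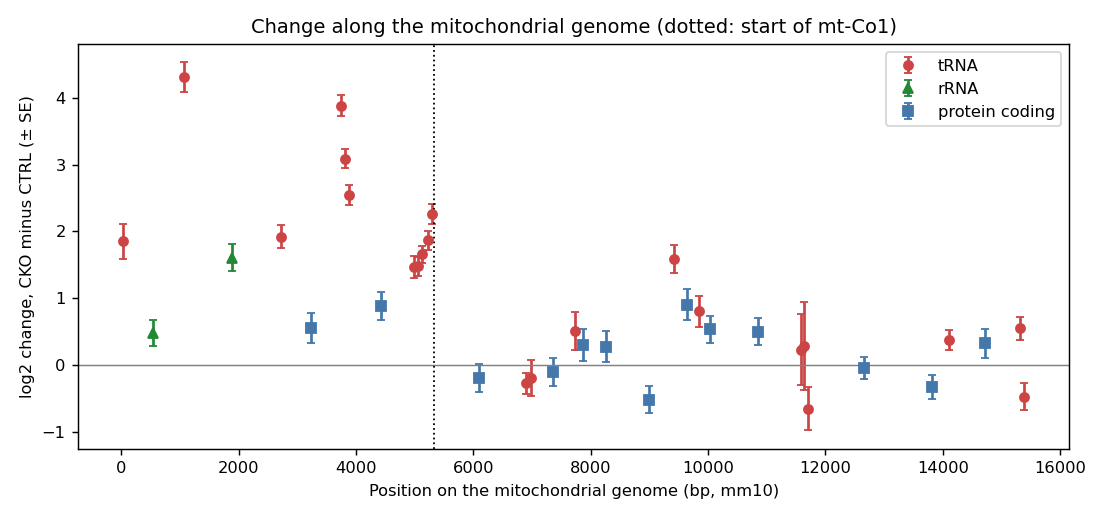
Log2 change (± SE) of each tested mitochondrial feature at its position on the mitochondrial genome (tRNA red circles, rRNA green triangles, protein coding blue squares; dotted line, start of mt-Co1). Of 15 features before that line 12 passed the limma threshold, with mt-Tv highest at 4.31; of 22 from it onward, 1 passed.

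The largest remaining rises were Vgll2, a TEAD cofactor listed at 0 in both CTRL libraries and at 34.7 and 28.4 TPM in CKO, and Tac2, a tachykinin precursor listed at 0 in CTRL and at 23.7 and 10.01 TPM in CKO. Fam171b rose 27.3-fold to 51.3 ± 4.82 TPM (SD, n = 2), or 18.3-fold without CTRL replicate 1 and 53.9-fold without CTRL replicate 2. Ddit4l, an mTOR inhibitor, reached 15.3 ± 2.81 TPM, Lor, which encodes loricrin of the skin barrier, 14.9 ± 1.79 TPM, and Hspb1, a small heat shock protein gene, 28.3 ± 18.2 TPM (SD, n = 2 each), from group means under 1 TPM. Vgll2, Tac2, Lor and Ddit4l fell under the filter without either CKO library and were then not tested. The largest falls were Lrrn3 (log2 change -3.63, SE 0.373), Cftr, the chloride channel of airway epithelium (-3.56, SE 0.438), Serpinb6b (-3.52), Tgm2, a transglutaminase (-3.42), the noncoding Snhg17 (-3.37), Clu, which encodes clusterin (-3.26), Hist1h4n (-3.21), Hist1h4m (-3.03), Cym (-2.90) and Il15, a cytokine gene (-2.84). Cftr went from 20.9 ± 4.73 to 0.903 ± 0.698 TPM (SD, n = 2 each). Hist1h4n and Hist1h4m belong to a family of near-identical histone genes, so their values are uncertain, and both fell under the filter without either CTRL library. Cym did not pass without CTRL replicate 1 (log2 change -2.77), nor Il15 without CTRL replicate 2 (-2.40). Hspb1, Snhg17 and Clu did not pass with a pseudocount of 0.1. Without CKO replicate 1 and without CKO replicate 2 the log2 change was -2.31 and -4.21 for Clu, -2.78 and -3.96 for Snhg17, and 3.25 and 4.61 for Hspb1, which stood at 3.15 without CTRL replicate 1 and 4.72 without CTRL replicate 2.

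The authors' deposited table marked 1591 genes, 918 up and 673 down. Of the genes called by limma, 118 of 127 higher ones were up and 115 of 116 lower ones were down in the authors' deposited table, and 0 had the opposite direction. Every marked gene had a deposited adjusted p under 0.05 and a fold of at least 1.5. That rule gave 1659 genes on recount, and the 68 further ones all had a deposited baseMean of 24.9 or less. In 16 genes marked up in the authors' deposited table, TPM was 0 in both CTRL libraries and in 1 of the CKO libraries. For Ctcf the authors' deposited table gave a log2 fold change of -1.25 and an adjusted p of 2.28e-08. Hspb1, called higher by limma, had an adjusted p of 0.273 in the authors' deposited table.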

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

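The fits without X and Y genes, with TPM rescaled without mitochondrial genes, and the recount of the deposited calls (1659) were chosen after seeing the data. None of 49 named genes past the threshold changed direction in any setting run, and 26 stayed past it in every setting that tested them but the one without a trend. Ctcf fell in every setting; it no longer passed with a pseudocount of 0.1 (-1.37), without a filter (-1.35), without a trend (-1.35) and rescaled without mitochondrial genes (-1.26), and its log2 change ran from -1.74 to -0.96 when 1 library was left out. Leaving out 1 library gave 125 to 1268 changed genes, 77 to 290 higher and 31 to 978 lower; the larger counts came without a CKO library, where the remaining one was assumed to vary like the CTRL pair. Of the 243 genes, 113 and 112 were kept without CTRL replicates 1 and 2, and 221 without either CKO replicate. Without a trend 8 genes passed, 6 higher and 2 lower. The lower genes numbered 70 with a pseudocount of 0.1 and 74 without a filter. The authors' deposited table had 1591 genes, 918 up and 673 down. Apart from the fits with fewer samples, the cause was not tested.

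The number of lists past the threshold was 0 with an estimated correlation and 1 with fry, and 4 to 9 when 1 library was left out. Replicate numbers are shared between the groups, but the labels give no pairing, and deviations of same-numbered libraries had a correlation of -0.0131 across genes. With the replicate block 254 genes passed (124 higher, 130 lower) and 7 lists did; in this balanced design the block leaves every log2 change as it was by construction, and among called genes named here, Cldn10, Ccno and Bnip3 lost their calls with the block. Genes that were not called gained a call (Fgfr2, Bmp4, Epcam, Nkx2-1) or changed sign in some settings. Id2 was at 0.033 with median-ratio scaling, 0.062 in the authors' deposited table, 0.0082 rescaled without mitochondrial genes, and -0.21 to 0.034 without 1 library. Mycn was at 0.051 with quantile scaling, 0.070 with median-ratio scaling, 0.072 in the authors' deposited table, 0.045 rescaled, and -0.32 to 0.22 without 1 library. Mki67 was at 0.048 in the authors' deposited table and at -0.71 to 0.45 without 1 library, and mt-Co1 at -0.43 to 0.055. Depth limits per library are unknown, since TPM keeps no counts and baseMean has no value per library. A count model was not run.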

Other observations

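The tests of the neighbour explanations, the mitochondrial tests and the comparison with whole lung were chosen after the pattern was seen. The neighbour test itself and the motif test were set beforehand. The test of further club cell genes was set before those genes were looked at. It came after other club cell transcripts had been seen in CKO replicate 2. Transcripts of mature airway cells were high in single CKO libraries. The genes of this paragraph other than Krt5 were named after their values were seen. Scgb1a1, the main secretory protein of club cells, stood at 0, 1.42, 0 and 2150 TPM in CTRL replicates 1 and 2 and CKO replicates 1 and 2. Scgb3a2 stood at 96.1 TPM and Cyp2f2 at 59.4 TPM in CKO replicate 2, against 4.49 TPM or less in the others. In CKO replicate 1 the basal cell keratin Krt5 stood at 55.8 TPM and Krt15 at 42.4 TPM, against 4.33 and 1.77 TPM in CKO replicate 2. In CTRL replicates 1 and 2 Krt5 was at 0 in both, and Krt15 was at 2.95 and 7.75 TPM.

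RNA of whole mature lung would bring its abundant surfactant transcripts at levels far above those seen beside 2150 TPM of Scgb1a1: Sftpc differed by -7.95 TPM between CKO replicate 2 and CKO replicate 1. In CKO replicate 2 Sftpa1 (14.6 TPM) lay within the CTRL range of 7.50 to 19.04 TPM, while Sftpb (54.1 TPM) and Hp (28.8 TPM) lay above the highest other library (39.9 and 5.80 TPM). Club-like cells, or RNA from them, remain a candidate source, although of 7 further club cell genes above 0, 4 were highest in CKO replicate 2 (one-sided exact binomial p = 0.0706), which missed the threshold. By the rule set before these further genes were looked at, this result counted against club-like cells or their RNA. Only after it was seen was the test judged unable to decide. The reasons were that 5 of the 7 stayed under 5 TPM in every library, and that Aldh1a1 and Cckar were already at 27.8 TPM or more in CTRL. In CKO replicate 2 both were below either CTRL library. Aldh1a1 stood at 12.3 TPM there and at 19.8 TPM in CKO replicate 1, and Cckar at 28.6 and 26.1 TPM. Whether such cells arose in the tissue or entered the sample cannot be told apart here.

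Among 12657 pairs of adjacent, non-overlapping nuclear genes, 74 had both members marked up in the authors' deposited table, against a mean of 34.5 in 10000 shuffles of the calls, and 102 were marked in the same direction, against 54.9 (permutation p = 0.0001 for each, the smallest these can give). Pairs marked down numbered 28 against 20.4 (permutation p = 0.0613) and opposite pairs 56 against 53.1 (permutation p = 0.355), but at 10 kb or more apart both exceeded shuffles within 20 bins of mean TPM, with 22 against 13.8 (permutation p = 0.023) and 47 against 36.1 (permutation p = 0.0413). A shared expression level, reads running on into the next gene, and paralogs may each produce such pairs, yet the excess marked up stayed in the binned shuffles (34.3 pairs), for pairs at least 10 kb apart (59 against 23.5) and without pairs sharing the first 3 letters of their symbols (67 against 32.5), each with a permutation p of 0.0001. The shuffles did not keep the distance between genes, and opposite pairs at 10 kb or more exceeded them too. The spacing of marked genes may therefore account for part of the excess at that distance. Among limma's calls 2 adjacent pairs were both higher and 6 both lower, which were not compared with shuffles. An excess of higher pairs is therefore not shown for limma's calls. The lower pairs included H19 with Mrpl23, and Krt8 with Krt18, Hist1h4m with Hist1h4n and Serpinb6b with Serpinb9, which share their first 3 letters. Mrpl23 and Serpinb9 were named after their values were seen. Domain-wide regulation is a hypothesis that was not tested, and neighbours with shared regulation unrelated to CTCF would give the same pattern.

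The hypothesis that genes marked down carry a CTCF-like motif near their start was not borne out. The core CCASYAGRKGGCRS, with up to 1 mismatch on either strand, was in the first 500 bases of the longest transcript of 15 of 580 genes marked down (2.59%) and 262 of 13131 unmarked genes (2.00%; Fisher's exact p = 0.292). The share among genes marked up, looked at afterwards, was 30 of 766 (3.92%; Fisher's exact p = 0.00101), and the reversed motif gave 0.783% there and 0.777% in unmarked genes. Promoters and distal elements were not searched.

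The rise of mitochondrial RNA may depend on position, mainly among tRNA features. The 15 features before mt-Co1 had a median log2 change of 1.85 and the 22 from mt-Co1 onward one of 0.28, a difference of 1.57; that split was placed after the values were seen, and the largest difference over all splits with at least 5 features on each side gave a permutation p of 0.031, across features that are not independent. More mitochondrial RNA as a whole would raise both alike. Small feature size would raise tRNAs at any position, but 11 tRNAs before mt-Co1 exceeded 11 after it by 1.63 in median log2 change. No p-value was computed for that difference. The largest difference over all splits of the tRNAs was 2.54 (permutation p = 0.00338), and it lay at a split other than mt-Co1. Since tRNAs were 11 of the 15 features and 11 of the 22, the medians of all features also differ by feature type. Before mt-Co1, mt-Rnr1 (0.48), mt-Nd1 (0.56) and mt-Nd2 (0.89) did not pass. After it, mt-Nd3 (0.91), mt-Nd4l (0.54) and mt-Nd4 (0.50) rose alike, and the other protein-coding features ran from -0.51 to 0.33. The glycine tRNA mt-Tg, also after mt-Co1, passed with a log2 change of 1.59 (limma adjusted p = 0.00798). That is above mt-Tw (1.47) and mt-Ta (1.48) before mt-Co1. The other tRNAs after mt-Co1 did not pass. Unprocessed transcripts from the first part of the genome may be a candidate source, which was not tested, and reads shared with nuclear copies of mitochondrial DNA stay open.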
